A study of Mus musculus with 60 samples.

How the data were processed

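The series holds 60 mouse samples of the ICR strain, from embryos of 3 stages (7.5, 7.0 and 6.5 days of gestation). The 6 RNA libraries were analysed here, and the other 54 samples (18 H3K27me3 ChIP, 18 ChIP input and 18 reduced representation bisulfite libraries, each in 9 groups) were not analysed here. Per the labels' protocols, embryos were kept in explant culture in N2B27 medium for 48 hours with EPZ005687, an inhibitor of the histone methyltransferase EZH2, or with the same volume of its solvent DMSO. RNA came from anterior embryonic (A), posterior embryonic (P) and extraembryonic (ExE) tissue. The labels give neither the stage of the RNA embryos nor the number pooled in a library.

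The deposited table holds a whole-number read count per gene and library, not normalized, which was settled from the values since the totals differ between libraries. The submitters' processing notes name CASAVA 1.8, TopHat2 2.0.9 and BWA and the genome build mm10. Which tool made these counts, whether strand was used, and the gene annotation are not given in the sources used here. Genes are given by symbol. Of 23154 entries, 27 carried dates in place of a symbol, as spreadsheet programs write them, and were left out; they held between 0.162% and 0.961% of a library's counts. Of the 23127 genes left, 23009 (99.5%) matched the RefSeq gene table of GRCm38.p6, the same assembly as mm10, by symbol or synonym, and coordinates come from it.

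Totals per library ran from 1000342 to 5812535 counts. A count of 0 allows up to 3 counts, which is 0.516 CPM (counts scaled to a library total of 1e+06) in the deepest library and 3 CPM in the shallowest. Intervals from counts cover counting error only. Each region and treatment has 1 library, so the regions or the arms stand in for repeats. The p-values measure the spread between these 6 libraries, estimated largely from all tested genes together.

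Genes with 10 or more counts in at least 2 libraries were tested (13744). Counts were scaled by TMM and fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test, region and treatment as additive terms and 2 residual degrees of freedom. From that fit came the contrasts EPZ005687 versus DMSO, ExE versus the mean of A and P, and P versus A. A fit with an added term for treatment in ExE, with 1 residual degree of freedom, gave the difference in treatment effect between ExE and the embryonic regions. In that fit A and P share 1 treatment effect. In both fits a gene's variance is drawn toward that of all genes. Its p-value can therefore be far smaller than 2 or 1 residual degrees of freedom alone would give. Adjusted p-values are Benjamini-Hochberg values, with a threshold of 0.05. Standard errors (SE) are the log2 fold change divided by the square root of the F statistic. For each region alone, log2 ratios of TMM-scaled CPM used a prior count of 2, with 95% conditional exact binomial intervals of the counts and no test. A fold against a library with 0 counts was taken against a floor of 3 counts in that library on the TMM scale; the floor leaves out the counting error of the other library, so the 2-sided interval reaches somewhat lower. In tests on simulated counts with known changes, the treatment contrast recovered 16 of 50 genes changed 8-fold and 30 of 50 changed 32-fold, with 1 false call among 11488 genes. For ExE versus embryonic it was 16 and 30 with 11 false calls among 11749 genes. For P versus A it was 2 and 23 with 0 false calls among 11767 genes, and for the interaction 0 and 10 with 3 false calls among 12367 genes. At 4-fold 3, 3, 0 and 0 of 50 genes were recovered in the same order, and at 2-fold 0 in each, so changes of that size were mostly missed. For ExE versus embryonic and for the interaction, false calls made up more than 0.05 of all calls, so genes that pass there can hold more false ones than the threshold states.

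Before the data were examined, 41 gene lists (cell type markers, chromatin complexes, imprinted genes, signalling targets, stress and housekeeping groups), the tests, the alternatives and the rule for named genes were fixed; a list of olfactory and vomeronasal receptors was added afterwards. The 40 lists with 3 or more tested genes, the added one among them, were tested with camera (limma 3.58.1) on voom values with a preset correlation of 0.01, adjusted over the lists. In each region a list's median log2 ratio was ranked among medians of 10000 random lists matched on size and expression. Random lists leave out that members of a list can move together, so an extreme percentile is no test. Named genes were the 10 largest changes in each direction past the threshold, with one sign in all compared library pairs and a mean CPM of 5 or more. Where fewer than 5 passed, the 5 smallest p-values were taken as values. Added to these were up to 4 called members per list, list members given as values, 17 genes always given, the 5 largest ratios each way per region among genes with 100 or more counts over its libraries, and the 5 smallest interaction p-values. Some genes that this rule names are not reported here. Other genes named were chosen after their values were seen: Gapdh, Ppia, Actg1, Tubb5, Eef1a1, Rn45s, Mrgpra6, Lin28b, Acta2 and markers of blood cells outside the lists.

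Alternatives were DESeq2 1.42.0 size factors or library totals for scaling, other filters on low counts, DESeq2's Wald test, limma-voom, fits without the region or treatment term, subsets of libraries, leaving out each library in turn, camera with an estimated correlation, and fry. Thinning all libraries to 1000342 counts, and leaving out Actb, Rn45s and Mrgpra6, were added after seeing the data.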

Results

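RNA from cultured mouse embryo explants was compared between the EZH2 inhibitor EPZ005687 and its solvent DMSO. EZH2 is the catalytic subunit of Polycomb repressive complex 2 (PRC2), which places H3K27me3. Each of the anterior embryonic (A), posterior embryonic (P) and extraembryonic (ExE) parts gave 1 library per treatment. Totals were 1780304 (A), 3413049 (P) and 5812535 (ExE) counts with DMSO, and 1000342, 2173284 and 1995240 counts with EPZ005687. A code in the deposited column names was shared by the 3 libraries of an arm and differed between the arms, so any difference in handling that goes with it cannot be separated from the treatment. The 3 regions of an arm may have come from the same embryos, which the labels do not say, so a mean and SD with n = 3 are over regions and not over repeats of the treatment.

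The first comparison asks how the EPZ005687 libraries differed from the DMSO libraries across the 3 regions. With EPZ005687, 203 genes fell and 7 rose among 13744 tested (edgeR, adjusted p under 0.05, 1219 at an unadjusted p under 0.05), and the 203 were lower in each of the 3 regions, with a median log2 fold change of -3.49. Actb, cytoplasmic beta-actin (chromosome 5, 142903115 to 142907976), stood at 48000 ± 3710 CPM (SD, n = 3) with DMSO and 973 ± 337 CPM (SD, n = 3) with EPZ005687, a log2 fold change of -6.09 (SE 1.24, edgeR adjusted p = 0.03). Slc39a1, a zinc transporter (chromosome 3, 90248190 to 90253613), fell by 6.51 on the log2 scale, from 2000 ± 743 to 30.6 ± 15.2 CPM (SD, n = 3, edgeR adjusted p = 0.004). The log2 fold change was -6.05 for the deacetylase gene Sirt6, -5.81 for the RNA demethylase gene Alkbh5, -5.70 for the KDEL receptor gene Kdelr2, -5.62 for Arglu1, -5.61 for Pxdc1 and -5.60 for the small GTPase gene Rap2b. It was -5.49 for the FGF signalling antagonist Spry2 and -5.47 for the imprinted receptor gene Igf2r. The gamma-actin gene Actg1, a close paralog of Actb with which reads can be shared, had a log2 fold change of 0.54 (SE 0.64, edgeR adjusted p = 0.89). DESeq2 called 428 genes lower and 144 higher, and limma-voom 365 lower and 32 higher. Without P DMSO the count of called genes in edgeR was 330, with A and P only it was 89, without a filter on low counts 349, and with library totals as the scaling it was 109. For Actb, the adjusted p in edgeR was 0.21 without A DMSO, 0.053 without ExE DMSO, 0.2 without A EPZ005687, 0.19 without P EPZ005687, 0.079 with A and P only and 0.058 with library totals, while over all alternatives its log2 fold change lay between -6.39 and -5.61. Without the region block the adjusted p of Pxdc1 was 0.067.

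**Figure D1:**
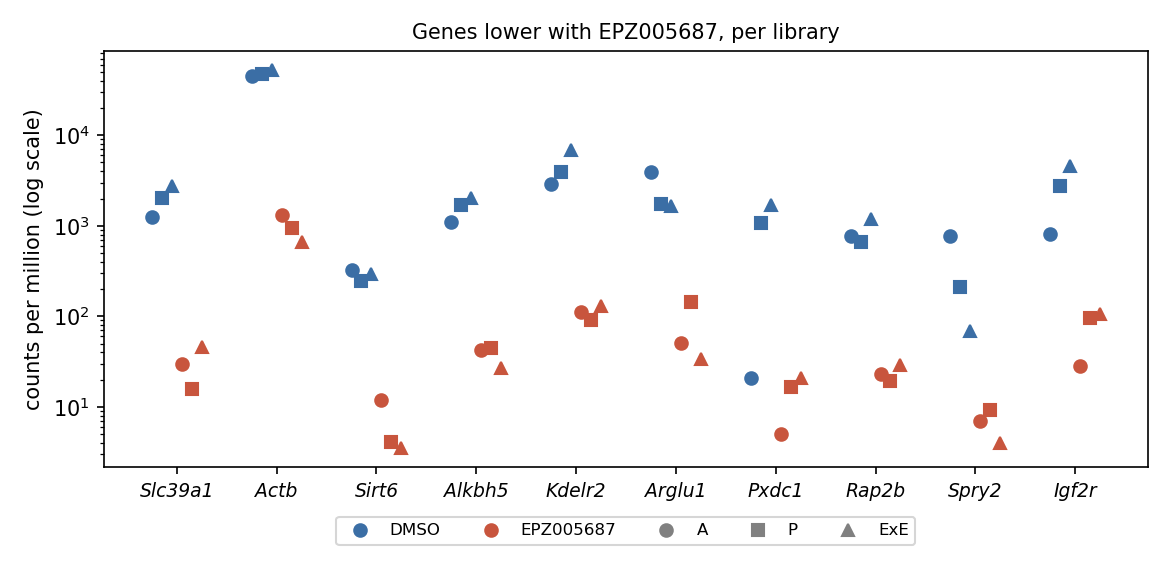
CPM on a log axis of the 10 genes with the largest called decreases with EPZ005687, 1 point per library, with colour for treatment and shape for region. Actb lies at 44700 to 52000 CPM with DMSO and at 657 to 1330 CPM with EPZ005687.

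Among genes of the lists fixed beforehand, the H3K27 demethylase gene Kdm6b fell by 5.06 on the log2 scale (edgeR adjusted p = 0.004), and it was the 1 of 4 demethylases and acetyltransferases that passed over all genes and adjusted over the list alone. In the epiblast and pluripotency list 2 of 14 genes fell over all genes and 2 adjusted over the list alone, with log2 fold changes of -4.57 for Lin28a, a regulator of let-7 processing, and -3.85 for the pluripotency factor Sall4. In the cholesterol list 3 of 18 fell over all genes and 3 adjusted over the list alone, with log2 fold changes of -4.29 for Sc5d and -3.58 for Insig1, which holds back sterol synthesis. Called decreases were also found for the Wnt targets Znrf3 (-3.32) and Ccnd1 (-2.88), the Nodal target Skil (-2.85), the glycolytic gene Hk2 (-3.06), the imprinted gene Impact (-2.98), Foxn3 (-3.41) and Foxn2 (-3.39). Without A DMSO the edgeR adjusted p was 0.054 for Sall4, 0.065 for Ccnd1, 0.1 for Skil and 0.1 for Impact, and without ExE DMSO it was 0.059 for Ccnd1, 0.064 for Hk2 and 0.074 for Foxn2. Without A EPZ005687 it was 0.057 for Sall4, 0.053 for Ccnd1, 0.11 for Skil, 0.053 for Hk2 and 0.13 for Impact. Without P EPZ005687 it was 0.055 for Skil, and without ExE EPZ005687 it was 0.071 for Insig1, 0.075 for Ccnd1, 0.084 for Hk2, 0.055 for Impact and 0.075 for Foxn2. With library totals it was 0.051 for Insig1, 0.079 for Ccnd1, 0.11 for Skil and 0.079 for Impact. With A and P only it was 0.05 for Znrf3, 0.12 for Ccnd1, 0.055 for Skil, 0.14 for Hk2, 0.11 for Impact, 0.11 for Insig1 and 0.13 for Foxn2, and without the region block it was 0.15 for Ccnd1 and 0.07 for Skil.

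None of the 9 tested PRC2 subunits passed singly. Ezh2 had a log2 fold change of -1.22 (SE 0.48, edgeR adjusted p = 0.45), with 350 ± 87.9 CPM with DMSO and 197 ± 21.6 CPM with EPZ005687 (SD, n = 3). Suz12 had -1.04 (SE 0.52) and Eed 0.20 (SE 0.49). As a list the subunits were lower in camera (7 of 9 negative, median log2 fold change -0.81, adjusted p = 0.041, and adjusted p = 0.83 with an estimated correlation). Ribosomal protein genes were higher (64 of 70 positive, median 0.91, camera adjusted p = 1.1e-17, adjusted p = 0.83 with an estimated correlation) and took 5.42%, 13.3% and 4.37% of counts in A, P and ExE with EPZ005687 against 2.84%, 3.12% and 2.22% with DMSO. The 45S ribosomal RNA precursor Rn45s moved alongside, at 1.44%, 6.54% and 0.521% with EPZ005687 against 0.109%, 0.0538% and 0.0853% with DMSO. Extracellular matrix and mesenchyme genes were higher in camera (13 of 17 positive, median 1.2, adjusted p = 0.036). Parietal endoderm (median -0.12, adjusted p = 0.026), other imprinted genes (median -0.19, adjusted p = 0.043) and epiblast genes (median -0.31, adjusted p = 0.012) were lower in camera. So was the cholesterol list (adjusted p = 0.045), although its median was 0.22 and its mean -0.54. Each of these list calls had an adjusted p = 0.83 with an estimated correlation. Of 40 lists, 8 passed in camera, and fry called 0 (smallest adjusted p = 0.16). PRC1 subunits (camera adjusted p = 0.93), the DNA methylation machinery (0.085), the integrated stress response (0.94), heat shock genes (0.64) and the olfactory and vomeronasal receptors (0.43) did not pass. The median over all tested genes was 0.20 with TMM and 0.63 with library totals, where the epiblast, parietal endoderm and other imprinted medians turned to 0.16, 0.30 and 0.25.

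Families of developmental regulators that PRC2 is known to repress did not pass as lists. Hox genes (4 of 39 tested, 2 positive) had a camera adjusted p = 0.94, the Pax, sine oculis-related, Lhx, Nkx and Irx families (10 tested, 7 positive, median 1.64) 0.70, and the T-box family (8 tested, 6 positive, median 1.11) 0.39. In the Gata and Fox families 2 of 22 fell and 0 rose over all genes, as they did adjusted over the list alone (camera adjusted p = 0.14). Cdkn2a, Elf5 and Hand1 lay below the filter on low counts.

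Of the 7 genes that rose, 5 lie on chromosome Y. Eif2s3y, a translation factor gene, had 57, 488 and 131 counts in A, P and ExE with EPZ005687 and 0, 0 and 1 with DMSO (edgeR adjusted p = 0.004). Gm20815 had 41, 17 and 103 against 0, 0 and 0 counts (edgeR adjusted p = 0.035), and as a predicted gene of a chromosome rich in gene copies its reads are uncertain. Uty (edgeR adjusted p = 0.012), Kdm5d (log2 fold change 6.11, edgeR adjusted p = 0.031) and Ddx3y (log2 fold change 5.75, edgeR adjusted p = 0.0096) made up the rest. Without P EPZ005687 the edgeR adjusted p was 0.16 for Uty, 0.6 for Kdm5d, 0.11 for Gm20815 and 0.05 for Eif2s3y; without ExE EPZ005687 it was 0.15 for Gm20815 and 0.062 for Kdm5d, and without P DMSO it was 0.074 for Kdm5d. With A and P only it was 0.17 for Gm20815 and 0.079 for Kdm5d. The list of Y-linked genes and Xist was higher in camera (5 of 6 positive, adjusted p = 0.0023, and adjusted p = 0.83 with an estimated correlation). Xist, the RNA that coats the inactive X chromosome in female cells, fell by 3.87 on the log2 scale, from 193 ± 61.8 CPM with DMSO to 21.3 ± 17 CPM with EPZ005687 (SD, n = 3, edgeR adjusted p = 0.0074). The 496 tested X-linked genes had a median log2 fold change of -0.23 and the 13213 autosomal genes 0.22. The 2 risers outside chromosome Y were Lars2, a mitochondrial leucyl-tRNA synthetase (log2 fold change 4.56, edgeR adjusted p = 0.014), and Actc1, cardiac actin (3.79, edgeR adjusted p = 0.03), whose CPM was 351 in P with EPZ005687 and 19.3 in P with DMSO. Lars2 took 0.181%, 0.162% and 0.0186% of counts in A, P and ExE with EPZ005687 against 0.00236%, 0.00434% and 0.00188% with DMSO. Rn45s was higher with EPZ005687 in each region as well. Whether all reads counted for Lars2 come from its own transcript was not tested. The edgeR adjusted p of Actc1 was 0.58 without the region block and 0.06 with A and P only. In A and ExE it had 0 and 2 counts with DMSO and 4 and 9 with EPZ005687. Without either P library it fell below the filter on low counts, so its call could not be checked without P.

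**Figure D2:**
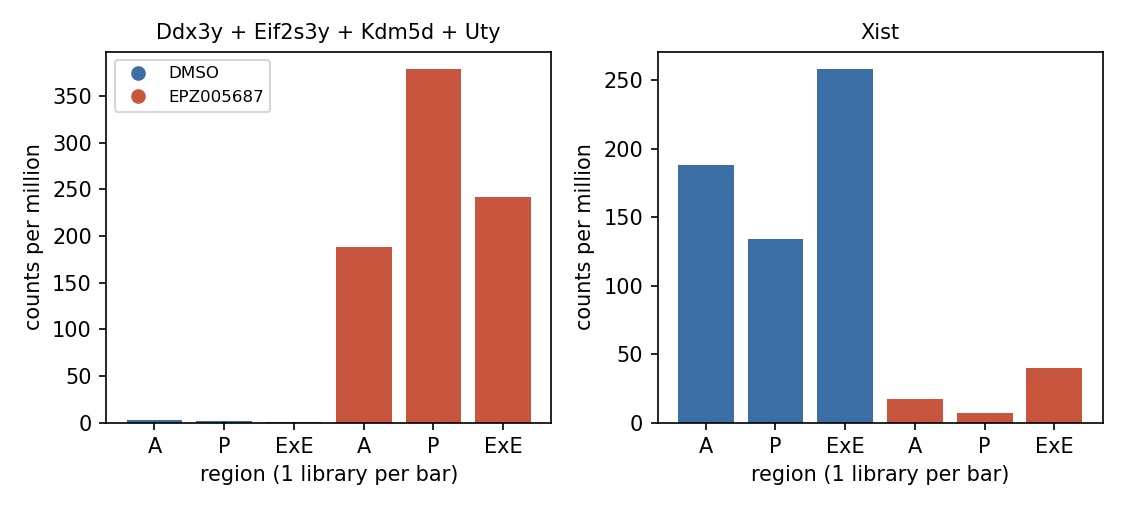
Left, summed CPM of 4 Y-linked genes; right, CPM of Xist; 1 bar per library, coloured by treatment. The Y-linked sum is 188 to 379 CPM with EPZ005687 and 1.03 to 2.25 CPM with DMSO, and Xist is 134 to 258 CPM with DMSO and 6.9 to 40.1 CPM with EPZ005687.

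ExE was set against the embryonic parts because the series concerns how these lineages part. Visceral endoderm genes, which mark the layer around the embryo and the later yolk sac, were higher in ExE (21 of 23 positive, median log2 fold change 2.13, camera adjusted p = 3.1e-17, and adjusted p = 0.55 with an estimated correlation). The secreted fetal protein gene Afp stood at 15800 CPM in ExE, 3760 CPM in P and 5.06 CPM in A with DMSO. With EPZ005687 it stood at 10200, 3900 and 2900 CPM. Parietal endoderm genes were higher too (12 of 13 positive, median 3.01, camera adjusted p = 5.9e-17, and adjusted p = 0.55 with an estimated correlation), where the basement membrane genes Col4a1 and Lamb1 had log2 fold changes of 4.15 and 3.29. Neural and anterior ectoderm genes were lower (0 of 11 positive, median -3.55, camera adjusted p = 3.4e-06, and adjusted p = 0.55 with an estimated correlation). Among them Otx2, a transcription factor of the forming head, stood at 193, 22 and 0 CPM in A, P and ExE with DMSO. With EPZ005687 it stood at 146, 33.6 and 2 CPM. The trophoblast progenitor list was higher in ExE in camera (10 of 16 positive, median 1.16, adjusted p = 0.02, and adjusted p = 0.60 with an estimated correlation). Key regulators of that lineage had few reads in ExE, where Cdx2 stood at 0 CPM in both arms, Elf5 at 0.172 and 3.01 CPM, and Eomes at 1.72 and 7.02 CPM with DMSO and EPZ005687. Ribosomal protein genes were lower in ExE (2 of 70 positive, median -0.76, camera adjusted p = 2.2e-11, and adjusted p = 0.63 with an estimated correlation). Integrated stress response genes (14 of 18 positive, median 0.78, camera adjusted p = 0.00069) and heat shock and immediate early genes (10 of 12 positive, median 1.55, camera adjusted p = 0.0028) were higher, each with an adjusted p = 0.55 with an estimated correlation. In all 18 lists passed in camera.

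No single gene passed in ExE versus embryonic in edgeR (0 of 13744, 882 at an unadjusted p under 0.05, smallest adjusted p = 0.131), against 242 with DESeq2 and 35 with limma-voom. Without P DMSO edgeR called 358, without A EPZ005687 388, without ExE EPZ005687 56, without ExE DMSO 21 and without A DMSO 6. Adjusted over the list alone, 9 visceral endoderm and 8 parietal endoderm genes were higher and 5 neural genes lower. Smallest edgeR p-values went to Lgals2 (log2 fold change 4.73, SE 0.66), the small heat shock protein genes Cryab (3.55, SE 0.57) and Hspb1 (4.10, SE 0.66), the apolipoprotein gene Apoa2 (6.15, SE 1.01) and Hkdc1 (4.45, SE 0.74) in the higher direction. In the lower direction they went to Chst2 (-6.27, SE 0.97), Otx2 (-6.68, SE 1.17), Sfrp1 (-5.03, SE 0.88) and Crabp2 (-4.25, SE 0.79), and to Stmn2, which was at 0 CPM in both ExE libraries. None of these 10 passed adjustment.

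P versus A sets the posterior against the anterior libraries of the embryonic part. With DMSO, P lay closer to ExE (Pearson's r over log2 CPM 0.87) than to A (0.69), while with EPZ005687 r was 0.70 and 0.72. Across the arms, A with EPZ005687 lay closer to P with DMSO (0.8) than to A with DMSO (0.7). For ExE with EPZ005687, r was 0.79 to P with DMSO and 0.76 to ExE with DMSO. P with EPZ005687 lay closest to P with DMSO (0.71) among the DMSO libraries. The primitive streak gene T stood at 19.3 CPM in P and 0 in A with DMSO, but at 48.8 and 203 CPM with EPZ005687. The differences below therefore cannot be read as anterior-posterior position alone. Visceral endoderm genes were higher in P (21 of 23 positive, median 3.25, camera adjusted p = 2.9e-19), as were blood and endothelium genes (19 of 19 positive, median 3.90, camera adjusted p = 3.8e-07). Cardiac and lateral mesoderm genes (12 of 12 positive, median 2.57, camera adjusted p = 8.1e-06) and BMP targets (9 of 10 positive, median 2.95, camera adjusted p = 9e-05) were higher in P as well. Neural and anterior ectoderm genes were lower in P (2 of 11 positive, median -2.58, camera adjusted p = 3.6e-07). Each of these 5 lists had an adjusted p = 0.53 with an estimated correlation. The smallest camera p was that of ribosomal protein genes, higher in P (68 of 70 positive, median 1.37, camera adjusted p = 5.1e-21, and adjusted p = 0.53 with an estimated correlation). They took 13.3% of counts in P with EPZ005687, where Rn45s took 6.54%, and 2.22% to 5.42% in the other 5 libraries. Olfactory and vomeronasal receptors were lower in P (27 of 95 positive, median -1.61, camera adjusted p = 4.3e-08, and adjusted p = 0.56 with an estimated correlation). In all 22 lists passed in camera. The eye and forebrain gene Pax6 stood at 181 CPM in A and 5.86 CPM in P with DMSO, and at 57 and 19.8 CPM with EPZ005687. The embryonic globin gene Hba-x, whose paralogs can share its reads, stood at 5820 CPM in P and 3.93 CPM in A with DMSO, and at 321 and 9 CPM with EPZ005687. The median over all tested genes was 0.12 with TMM and -0.11 with library totals.

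No single gene passed in P versus A in edgeR (0 of 13744, 744 at an unadjusted p under 0.05, smallest adjusted p = 0.0781), against 180 with DESeq2 and 23 with limma-voom. Without P DMSO edgeR called 230, without A EPZ005687 226, without ExE DMSO 96, without ExE EPZ005687 74 and without P EPZ005687 16. Adjusted over the list alone, 11 visceral endoderm, 3 blood and 4 cardiac genes were higher and 2 neural genes lower. The smallest edgeR p-values were those of Lgals2 (log2 fold change 7.55, SE 1.01), Actc1 (6.89, SE 1.01), S100a1 (6.49, SE 0.95), the imprinted gene Phlda2 (4.81, SE 0.71) and Apom (7.05, SE 1.10), all higher in P. On the lower side they were those of Peg12 (-3.68, SE 0.70), Tal2 (-5.68, SE 1.16), Sp8 (-7.05, SE 1.52), Sfrp1 (-3.37, SE 0.84) and Chst2 (-3.12, SE 0.79).

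**Figure D3:**
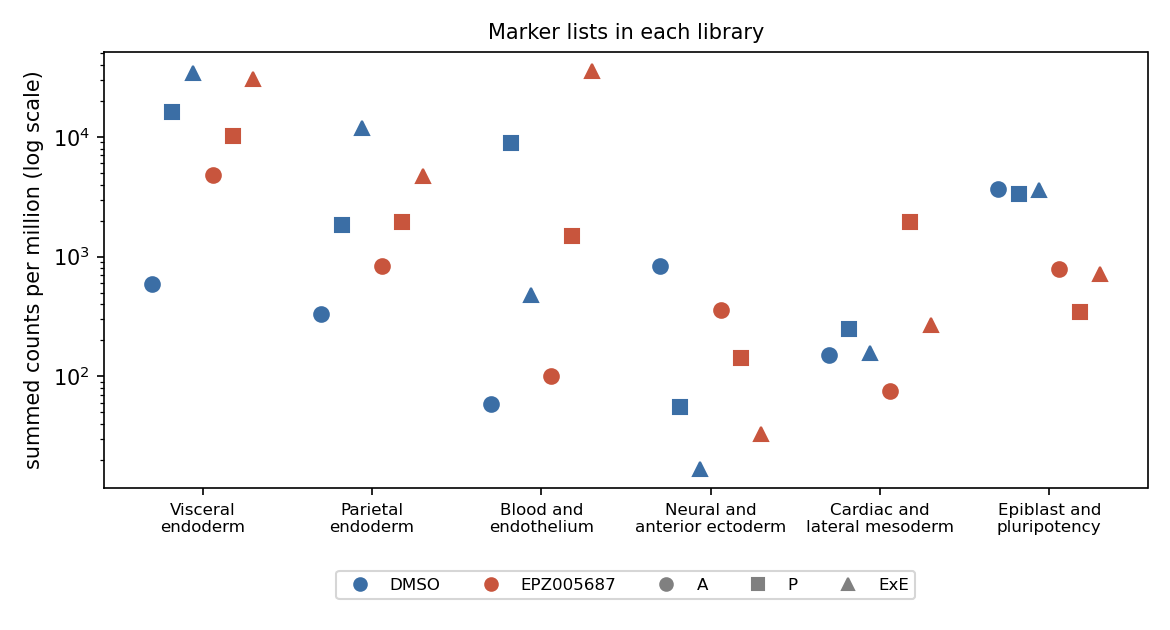
Summed CPM of 6 marker lists on a log axis, 1 point per library, with colour for treatment and shape for region. Blood and endothelium genes peak in P with DMSO (8980 CPM) and in ExE with EPZ005687 (35300 CPM), and visceral endoderm genes in A stand at 586 CPM with DMSO and 4850 CPM with EPZ005687.

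The treatment effect differed between ExE and the embryonic regions for 7 genes, all with a more positive effect in ExE (edgeR, 515 at an unadjusted p under 0.05). The fit gives A and P 1 shared effect, which did not hold for all of them. Its p-values rest on a variance pooled over genes, so that disagreement within a gene hardly enters them. Log2 ratios in A, P and ExE were -1.09, -3.83 and 6.29 for Hbb-y, -0.37, -3.85 and 6.11 for Slc25a37, and -0.74, -3.58 and 4.95 for Ube2l6. A and P lay closer for Lin28b (-1.07 and -1.33) and Acta2 (-0.48 and -0.22). The embryonic globin gene Hbb-y had a difference of 9.27 on the log2 scale (SE 1.83, edgeR adjusted p = 0.0027), with 4520 CPM in ExE with EPZ005687, 711 CPM in P with DMSO, 54.8 CPM in P with EPZ005687, 35.3 CPM in ExE with DMSO, and 5.62 and 3 CPM in A with DMSO and EPZ005687. The difference was 8.61 for Slc25a37, the mitochondrial iron importer of red cell precursors (SE 1.77, edgeR adjusted p = 0.0038), and 7.53 for Ube2l6 (SE 1.75, edgeR adjusted p = 0.045). Of the 7, 2 belong to the blood and endothelium list, 19 of whose genes were tested. Lin28b (8, SE 1.88) and the smooth muscle actin gene Acta2 (6.89, SE 1.63) passed with an edgeR adjusted p = 0.047 each. Scaled by library totals, edgeR called 0 genes, with adjusted p = 0.12 for Hbb-y, 0.17 for Slc25a37 and 0.23 for Ube2l6. DESeq2 called 16 and limma-voom 6, 4 of them among the 7. Thinned to equal totals, 3 passed in edgeR, with adjusted p = 0.054 for Ube2l6. The adjusted p of Ube2l6 was also 0.13 in edgeR without a filter on low counts and 0.053 in limma-voom.

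Within single regions, without a replicate check, large ratios ran both ways. Libraries of the same region were not always the closest across the arms, so these ratios can hold differences in tissue as well. Among 13744 genes, 4440 were at least 1 log2 unit higher and 3059 lower in A, 3591 and 3669 in P, and 3962 and 2955 in ExE. With library totals as the scaling the numbers were 5596 and 2133 in A, 4043 and 3282 in P, and 5792 and 1558 in ExE. In A the largest ratios were those of Afp (2900 CPM against 5.06), the primitive streak gene T (203 counts against 0, at least 90.2-fold higher), Chmp2b (at least 61.3-fold), Hyal2 (at least 56.9-fold) and the retinol carrier Rbp4 (592 CPM against 2.81). Visceral endoderm genes in A had a median log2 ratio of 1.87, at percentile 100 of the random lists. The lowest ratios in A were those of Spry2 (log2 ratio -7.01, 95% exact interval -8.52 to -6.16), Arglu1, Mrgprb1, Sp8 and Rbm15.

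In P the largest ratios were those of the atrial myosin genes Myl7 (1704 counts against 1, log2 ratio 9.48, 95% exact interval 8.76 to 16.54), which lay below the filter of the tests, and Myl4 (535 counts against 0, at least 253-fold higher). Eif2s3y (at least 230-fold), Rn45s (log2 ratio 6.77) and Wfikkn1 came next. Among the lowest were Slc39a1 (-7.11), A130010J15Rik (0 counts against 208, at least 49-fold lower), Klf14 and Gm2a. Blood and endothelium genes had a median log2 ratio of -1.66 in P, at percentile 0, and 3.72 in ExE, at percentile 100. Among the largest ratios in ExE were those of Arl4a, Tspan32 (231 CPM against 0.86), the red cell antigen gene Kel (at least 95.4-fold higher) and the erythroid factor Gfi1b (at least 93.6-fold). The lowest were Nck2 (at least 152-fold lower), Actb, Pxdc1, Alkbh5 and Sirt6. Parietal endoderm genes in ExE had a median log2 ratio of -1.92, at percentile 0. Members of these lists moved together (estimated correlation 0.522 for blood and endothelium and 0.512 for parietal endoderm), which the random lists leave out.

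The fold changes of the regions were weakly related. Across 13744 genes, which are not independent replicates, Pearson's r was 0.17 between A and P, 0.12 between A and ExE and 0.28 between P and ExE (Spearman's rho 0.15, 0.11 and 0.25). Over the 1287 genes with 100 or more counts in every library, r was 0.51, 0.66 and 0.54. One sign in all 3 regions was found for 33.4% of genes, where chance gives 25%.

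None of the genes always given passed in any of the 3 contrasts. For EPZ005687 versus DMSO the log2 fold changes were 1.79 (SE 2.12) for Pou5f1, -0.63 (SE 1.25) for Sox2, 0.45 (SE 0.78) for Otx2, -1.06 (SE 0.54) for Dnmt3b, -0.07 (SE 1.69) for Dnmt3l, 0.78 (SE 0.85) for Gata4, -0.80 (SE 0.95) for Gata6, 0.75 (SE 1.51) for Bmp4, 1.46 (SE 1.66) for Eomes, 3.05 (SE 1.65) for T and -0.81 (SE 3.49) for Cdx2.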

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

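The tests of the place and the amount of blood cells were chosen after the results were seen, and the test of the difference between regions was not.

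Erythroid genes stood out because the test of the difference in treatment effect between ExE and the embryonic regions passed for some of them. The difference was 9.27 on the log2 scale for Hbb-y and 8.61 for Slc25a37 (edgeR, 1 residual degree of freedom, variance pooled over genes). Ube2l6 (7.53), which is not among the erythroid markers used here, passed as well. Globin RNA differed in place between the arms: the log2 ratio of ExE to P was -4.51 for Hba-x and -3.36 for Hbb-bh1 with DMSO, and 5.82 and 2.52 with EPZ005687, a difference that was not tested. One candidate explanation is that the same kind of blood cells was dissected with P in the DMSO embryos and with ExE in the EPZ005687 embryos; the log2 ratio of ExE with EPZ005687 to P with DMSO should then be similar over erythroid genes, and its SD was 1.04 over 17 genes (7 of them in the blood list), against 1.16 over 10285 other genes, which leaves it open. More blood cells with EPZ005687 is another: summed erythroid CPM was 4.02 times that with DMSO, but with 1 library per region and arm this cannot be told apart from embryo-to-embryo differences in stage or dissection. Hba-x, the most abundant of these genes, stood at 23200 CPM in ExE with EPZ005687 and 5820 CPM in P with DMSO.

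Lin28b (8) and Acta2 (6.89), which passed the same test, are not erythroid genes; Lin28b was at 0.172 CPM in ExE with DMSO and 37.1 CPM with EPZ005687.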

How the results depend on the processing

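No paired analysis was possible because each RNA group has 1 library and no replicate numbers of its own; region is the block. Leaving out a library was not run for the interaction, since no residual degrees of freedom remain. The pseudocount alternative for normalized values was not run, since the table holds counts. Thinning and the removal of abundant genes were chosen after seeing the data. The causes of the differences below were not tested.

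For EPZ005687 versus DMSO, 210 genes became 109 with library totals, 349 without a filter on low counts, 572 with DESeq2 (144 higher, 428 lower), 397 with limma-voom and 89 with A and P only, and 170 to 330 with single libraries left out. For ExE versus embryonic, 0 became 210 without a filter, 242 with DESeq2, 35 with limma-voom and 0 to 388 with libraries left out. For P versus A, 0 became 140, 180 and 23 in the same order, 1 after thinning to equal totals, and 0 to 230 with libraries left out. With a library left out, the lone library of its region hardly enters the treatment estimate. Actb had log2 fold changes of -6.38 and -6.39 without A DMSO and without A EPZ005687. They were -6.2 and -6.21 for the P libraries and -5.64 and -5.62 for the ExE libraries, against -5.61 with A and P only. Leaving out 1 or the other library of a region is thus no separate check of the treatment. In the region contrasts the lone library is assumed to vary like the rest. The 7 interaction genes became 0 with library totals, 16 with DESeq2 and 3 after thinning. Estimated correlation and fry each left 0 of 8, 18 and 22 lists for the 3 contrasts. Between regions, r over genes with 100 or more counts was 0.51 (A and P), 0.66 (A and ExE) and 0.54 (P and ExE).

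Of the 31 called genes named for EPZ005687 versus DMSO, 288 of 309 values under other settings and 153 of 184 with a library left out kept sign and call, and none changed sign. Among named genes that had not passed, 27 of 199 values under other settings gained a call for ExE versus embryonic, and 25 of 184 for P versus A. Genes that had not passed changed sign as follows. For EPZ005687 versus DMSO: Cdx2 0.06 with DESeq2; Otx2 -0.18 with limma-voom, -0.59 without the region block and -0.15 with A and P only; Dnmt3l 0.34 with library totals and 0.71 after thinning. With libraries left out, Cdx2 ran from -6.54 to 2.79, Bmp4 from -0.07 to 1.56, Otx2 from -0.18 to 1.36, Dnmt3l from -0.78 to 0.43 and Gata6 from -1.79 to 0.29. For ExE versus embryonic, with libraries left out, Eed ran from -0.13 to 0.25, Suz12 from -0.80 to 0.26 and Eomes from -1.57 to 0.42. For P versus A: Eed -0.03 with library totals, Eomes 0.02 with limma-voom and 0.54 without the treatment term, T -0.39 with DESeq2 and -1.14 without the treatment term, Dnmt3b 0.03 without a filter. With libraries left out, Ezh2 ran from -0.36 to 0.09, Suz12 from -0.58 to 0.46, Cdx2 from -4.43 to 5.26, Eomes from -2.73 to 1.53, T from -1.85 to 9.22 and Dnmt3b from -0.35 to 0.19. Depth sets a floor of 3 counts, which is 3 CPM in A with EPZ005687.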

Other observations

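The tests of newly detected developmental genes, embryo sex, depth and library occasion, and the bound for the test of scaling, were chosen after the results were seen; the other scalings themselves and the count of other splits of the libraries were not.

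More genes were seen with EPZ005687. Thinned to 1000342 counts, the A, P and ExE libraries held 19576, 17006 and 18015 genes with a count, against 13901, 15536 and 12753 with DMSO. Of 149 Hox, Pax, sine oculis-related, Lhx, Nkx, Irx, T-box, Gata and Fox genes, 65.1%, 66.4% and 59.1% had a count with EPZ005687 and 31.5%, 49% and 28.9% with DMSO. A hypothesis is that developmental regulators held down by PRC2 become detected. They gained more than 1462 olfactory and vomeronasal receptor genes in 2 of 3 regions, by 33.6 against 32.5 percentage points in A and 17.4 against -1.6 in P, but 30.2 against 35.1 in ExE, so the test did not decide. The receptor genes took 0.536%, 0.21% and 0.319% of counts with EPZ005687 and 0.448%, 0.118% and 0.027% with DMSO, and the sensory neuron receptor gene Mrgpra6 alone 2.4%, 0.314% and 1.12% against 0.528%, 0.146% and 0.0403%.

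Contractile genes of the heart were high in 1 library. In P with EPZ005687, Myl7 reached 784 CPM, Tnni1 181 CPM and Tnnt2 117 CPM, where P with DMSO held 0.293, 22 and 6.45 CPM. Tnni1 and Tnnt2 were picked after their values were seen. Other members of the cardiac and lateral mesoderm list went both ways in P. Tbx20 stood at 80.5 CPM with EPZ005687 and 24.3 CPM with DMSO, Gata4 at 46 and 24 CPM, Gata6 at 40.5 and 21.7 CPM and Hand2 at 10.1 and 1.17 CPM. Level or lower were Isl1 at 17.5 CPM with EPZ005687 and 17.3 CPM with DMSO, Mef2c at 26.2 and 70 CPM, Smarcd3 at 8.74 and 9.67 CPM and Hand1 at 3.68 and 4.39 CPM. Over the 3 regions the list did not pass (8 of 12 positive, median log2 fold change 0.69, camera adjusted p = 0.084, and adjusted p = 0.83 with an estimated correlation). Other housekeeping genes did not follow Actb: Gapdh had a log2 fold change of 1.12 (SE 0.59), Ppia 1.46 (SE 0.83) and Eef1a1 -0.13 (SE 0.75), while the tubulin gene Tubb5 had -3.57 (SE 0.89, edgeR adjusted p = 0.092).

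The Y-linked genes and Xist may reflect embryos of different sex in the 2 arms. Ddx3y, Eif2s3y, Kdm5d and Uty together had 16 counts of 11005888 with DMSO and 1494 of 5168866 with EPZ005687, and the summed CPM with DMSO was 0.623% of that with EPZ005687, as a set of female embryos against a set with male embryos would give. The labels give no sex. The 4 genes had 4, 6 and 6 counts in A, P and ExE with DMSO, where Xist stood at 188, 134 and 258 CPM. With EPZ005687 they had 188, 824 and 482 counts. Female embryos hold no chromosome Y for a treatment to act on, and Xist acts in female cells. These values argue against a treatment effect alone, on embryos of 1 sex, for the Y-linked genes and Xist. A treatment effect on top of a difference in sex was not tested and stays open.

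The excess of lower genes lay among the calls. Over all 13744 tested genes, 2376 were higher and 2212 lower in all 3 regions. The excess among the calls was weighed against scaling, depth and handling, while transcript length, GC content and uneven coverage along transcripts were not tested and stay open. The share of lower genes among the calls was 93.6% at its lowest over both other scalings in edgeR, although with DESeq2's own test it was 74.8%. The other scalings moved the median log2 fold change over all tested genes from 0.20 to 0.25 and 0.63, while the called decreases ran from -2.28 to -6.51. Shifts of that size could not turn a called decrease into a rise, so the share could hardly fall and does not decide on scaling. With library totals 102 genes were called lower in place of 203. Depth is argued against because 97% of the 203 genes were still called and lower after thinning to equal totals (197 genes). A different occasion of library preparation or sequencing could also give such a difference. It cannot be told apart from the inhibitor, since 0 codes in the column names are found in both arms. The difference in embryo sex that the Y-linked genes and Xist point to goes with the arms in the same way. Of the 10 splits of the 6 libraries, 1, the real one with 210 genes, gave as many genes, and the highest other split gave 0; 6 of the 10 part only 1 region, so 4 compare all 3 regions as the real one does, which is too few for a share under 0.05.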
